A study of Mus musculus with 3 samples.

How the data were processed

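RNA was profiled in 3 libraries of mouse metaphase II oocytes of the ICR strain, named young, aged and aged-sec by the labels' titles. Per the labels' protocols, oocytes were collected at the germinal vesicle stage and matured for 16 to 18 h in M16 medium, with or without the secretome of human umbilical cord mesenchymal stem cells mixed 1 to 1. The treatment field of the labels names the secretome on all 3 samples, so the groups were taken from the titles. Each library was a pool of 20 oocytes from 4 mice, with SMART-Seq2 cDNA, transposon-based library construction and DNBSEQ sequencing, per the labels' protocols and the series' design text. The aligner, the quantification program and the genome build are not given in the sources used here, so no coordinates are printed.

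The authors deposited 1 table with TPM of RefSeq transcripts in each library, per the file headers, although its name speaks of raw counts. It also holds the authors' ratio of aged over young and of aged-sec over aged, per the file headers. These deposited ratios equal the quotients of the TPM columns within a relative difference of 6.6e-07. The table has 9126 rows, all of mRNA type, with 2 decimals. The lowest deposited aged over young ratio is 1.2 and 0 rows hold a zero, so the table is a part of each library selected on that ratio. Listed TPM summed to 229243 in young, 324814 in aged and 321460 in aged-sec oocytes, of a whole of 1000000. The transcripts outside the table were not analysed here. Selection on the aged over young ratio makes every aged value higher than young, and it favours aged values that are high by chance, so ratios of aged-sec over aged are drawn below 1 even without an effect. Values of 0.01 TPM are the smallest step of the table, and ratios against them are set by rounding.

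Of the rows, 4967 are curated transcripts, 3910 are predicted ones and 249 are second or later copies of an accession. There were 210 rows that shared accession and values with another row. Gene symbols are those of the table. Accessions of 8920 rows (97.74%) matched the RefSeq annotation of assembly GRCm38.p6, which was used only for the number of mRNAs per gene and the number of protein-coding genes. Of 21900 protein-coding genes 5996 (27.4%) had a listed transcript. Library size and depth are unknown from TPM, so no counting interval or floor was given. Precision is limited by 1 library per group.

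TPM were used as deposited. Log2 ratios had a pseudocount of 0.5 TPM in both libraries, which shrinks the ratio of low transcripts; ratios called aged over young or aged-sec over aged without "log2" have none. The size rule was a log2 ratio of at least 1 in size with at least 10 TPM in the higher library of the pair. The rule written before the data were examined assumed read counts, with a normalization and a counting interval that need them. It was applied to TPM without the interval, and minimums meant for scaled counts were read as TPM. The intended negative binomial simulation was replaced by noise on the log2 scale for the same reason. The unit of analysis was the transcript, and genes are counted by symbol.

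Named transcripts followed a rule written before the data were examined. For each comparison it took the 8 symbols on each side under the size rule with the largest log2 ratio, in place of the counting bound first intended, leaving out names such as Gm with digits, Rik or -ps. For each list it took up to 4 members under the size rule and the 2 members with the highest mean TPM. It always took Bdnf, Ntrk2, Ngfr, Mos, Mapk3, Btg4, Cnot6l, Cnot7, Gdf9, Bmp15 and Zp3. Some transcripts that the rule names are not reported here. The 20 gene lists and 6 marker lists were also fixed then, and 8 gene families were added after the data were seen. A list used 1 transcript per gene, the listed one with the highest mean TPM, detected at 1 TPM or more in at least 1 library (4320 genes). Its median log2 ratio was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, and a list stood apart under percentile 2.5 or over 97.5. The draw of random lists was repeated 20 times with other seeds, chosen after the data were seen, since 2 lists lay close to a limit. These percentiles describe the libraries and are not p-values.

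A transcript was nearer to young when its aged-sec log2 TPM, with nothing added, differed less from young than from aged. Intervals of shares are exact Clopper-Pearson at 95%. Both comparisons with aged share the aged library, so 100 sets of 3 unchanged libraries were simulated around the mean log2 TPM of each listed transcript and kept where aged over young was at least 1.2. The noise was normal, with a spread taken from the aged-sec over aged ratios in 20 expression bins, or resampled from the same ratios. The simulated overlaps between 2 comparisons were added after the data were seen. The spread of the noise includes any effect of the secretome, and transcripts outside the table could not enter the simulation.

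The rule was tested on simulated data, with 200 transcripts changed by known folds and normal noise of 0.2 on the log2 scale. The list percentile was tested on separate normal draws of log2 ratios, independent between genes and with the same spread at every expression level. For the aged against young pair, run on 9126 transcripts, the size rule recovered 12.5% of those changed 1.5-fold, 57.5% at 2-fold, 92.5% at 3-fold, 100.0% at 4-fold and 100.0% at 8-fold, and 0 of 1352 unchanged ones. For aged-sec against aged it recovered 7.5%, 50.0%, 92.5%, 97.5% and 100.0%, with 0 of 1986 unchanged ones. For aged-sec against young it recovered 7.5%, 35.0%, 100.0%, 100.0% and 100.0%, with 0 of 1352 unchanged ones. These values hold for noise of 0.2 only and do not give the rate of false calls in the data. The 3 unchanged libraries with resampled deviations gave a median of 23 transcripts (16 to 32) higher in aged than young by the rule. They gave 21 (13 to 29) lower in aged-sec than aged, and with normal noise 2 (0 to 6) on either count. A list of 20 genes shifted by 0.5 lay at percentile 100.0 in all 3 pairs, and of 100 unshifted lists 2, 3 and 4 stood apart in the pairs in the order given.

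Alternatives were other scalings of the listed transcripts (median-of-ratios and upper-quartile), TPM minimums, fold limits, removal of ribosomal protein genes, pseudocounts, list detection and unmatched random lists. Those chosen after seeing the data were curated transcripts only, removal of second copies, sums per gene, other pseudocounts for the counts, and for the share nearer to young no TPM minimum and removal of ribosomal protein genes. Scaling on the total, and the rule without a counting interval, are the same as the values reported. The planned trimmed-mean normalization needs counts and was not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.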

Results

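Poly(A) cDNA was sequenced from mouse oocytes of the ICR strain that had been matured in culture to metaphase II, the stage at which the egg waits for fertilization. There were 3 libraries: young oocytes, aged oocytes, and aged oocytes matured with secretome, the medium conditioned by human umbilical cord mesenchymal stem cells (called aged-sec here). Each library pooled 20 oocytes from 4 mice, so each group had 1 library. No value below therefore has a replicate error, no p-value is given, and every difference is one between libraries rather than between conditions. The table analysed holds TPM, transcript abundances scaled to a total of 1000000 per library, for 9126 RefSeq transcripts of 6104 gene symbols. Each of them had an aged over young ratio of at least 1.2 and a value above 0 in all 3 libraries. A transcript that was lower in aged oocytes could not appear, and the direction of the age comparison was fixed by the way the table was made. The listed transcripts held 22.9% of all TPM in the young library, 32.5% in the aged library and 32.1% in the aged-sec library. Sequencing depth is unknown because TPM keeps no read number, so no counting interval could be given for a transcript.

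The comparison of aged with young oocytes addresses by how much the listed mRNAs were higher in the aged than in the young library. Among the transcripts that met the size rule described below was Nlrp4f (NM_175290), a member of the oocyte NLR family, at 288 TPM in young, 742 TPM in aged and 650 TPM in aged-sec oocytes. Transcripts of Ythdf3 (NM_001145919), a reader of methylated mRNA, stood at 14.8 TPM in young and 38.6 TPM in aged oocytes. Crebbp (NM_001025432), a histone acetyltransferase, stood at 8.70 and 26.1 TPM. The size rule required at least a 2-fold ratio, with 0.5 TPM added to each value, and at least 10 TPM in the higher library. It was met by 398 transcripts of 342 genes among the 2186 with enough TPM, or 18.2%. No transcript was lower, as the table allows. The median aged over young ratio over the list was 1.71, with an interquartile range of 1.4 to 2.39.

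The transcripts with the largest age ratios were mostly single variants or second annotated copies of a gene. The second copy of Cd55 (NM_010016), a complement decay-accelerating protein, stood at 0.32 TPM in young and 109 TPM in aged oocytes, a log2 ratio of 7.06. The second copy of Farsb (NM_011811), a subunit of phenylalanyl-tRNA synthetase, stood at 0.55 and 104 TPM. Atad2 (NM_027435), a bromodomain ATPase, stood at 0.01 and 15.4 TPM, and a variant of Timeless (NM_001164081), a replication fork protein, at 0.02 and 15.2 TPM. The next were variants of Elmod2 (3.95 to 89.2 TPM), Crb3 (0.77 to 21.9 TPM), Foxj3 (0.13 to 10.2 TPM) and Zc3h14 (0.22 to 10.9 TPM). Of the 389 transcripts under the size rule whose accession matched RefSeq, 348 belonged to genes with several annotated mRNAs. That was 89.5%, against 82.3% of all transcripts with enough TPM. Reads of near-identical copies and of overlapping variants can be divided among them by the quantification, so these ratios are uncertain as measures of the gene.

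Gene groups were compared through 20 lists fixed beforehand, of which 19 had members at 1 TPM or more in at least 1 library. Because every listed transcript was higher in aged oocytes, a list was judged by the percentile of its median log2 ratio among 10000 random lists matched on expression. In the age comparison none of the 19 lists stood apart, where 0.95 would by chance. List members and random lists both held only genes with a transcript at an aged over young ratio of at least 1.2. The percentile therefore ranks the size of the excess among listed genes, and cannot show whether a whole pathway differed with age. The listed part of the 19 lists ran from 10 of 83 respiratory chain genes to 15 of 23 cohesin genes, against 27.4% of protein-coding genes. Whether these shares follow age or expression in oocytes was not tested. The median over all 4320 detected genes was 0.56. Oocyte maternal factors (16 members, 1 under the size rule) had a median of 0.51 at percentile 49.2. Their most abundant members were Rfpl4, at 3024 TPM in young and 4485 TPM in aged oocytes, and Omt2a, at 1737 and 2257 TPM. The maternal mRNA storage and decay machinery (30 members, 1 under the rule) had a median of 0.55 at percentile 50.8. A lower variant of the deadenylase gene Cnot7 (NM_011135), not the one entered in the list, met the rule at 6.56 and 31.1 TPM. The most abundant members were Cnot7 (NM_001271542), at 411 and 584 TPM, and Pabpn1l, a nuclear-type poly(A)-binding protein at 226 and 313 TPM. Cnot6l (NM_144910), another deadenylase of the same complex, stood at 53.5 and 67.4 TPM. Of Btg4, the adaptor that recruits this complex in the egg, the table held 2 predicted variants at 1.31 and 0.18 TPM in young and at 1.84 and 0.37 TPM in aged oocytes. The metaphase II arrest and cell cycle genes (22 members) had a median of 0.52 at percentile 55.0. None met the rule, including the most abundant, Cks2 (7430 and 8942 TPM) and Cks1b (3915 and 4767 TPM).

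The cohesin list (12 members) had the highest median of the fixed lists in the age comparison, 0.73 at percentile 93.4. With curated transcripts only it was 0.89 and stood apart (percentile 99.1), and with detection at 10 TPM it was 0.49 (percentile 42.5). Of these members 2 met the size rule. They were Nipbl, the cohesin loader, at 6.52 and 14.2 TPM, and Espl1, the protease separase, at 3.68 and 10.4 TPM. The most abundant members were Pttg1, the separase inhibitor securin (1388 and 1943 TPM), and Esco2 (407 and 514 TPM). The proteasome subunits (8 members) had the lowest, 0.37 at percentile 4.6, with Psma4 at 149 and 190 TPM and Psma6 at 36.6 and 59.5 TPM. Spindle and kinetochore genes (22 members) had a median of 0.48 at percentile 29.7, with the checkpoint kinase Ttk under the rule at 8.76 and 18.9 TPM. Aurkc, a meiotic Aurora kinase, stood at 512 and 715 TPM and Kif23 at 213 and 276 TPM. Chromatin regulators (20 members) had a median of 0.54 at percentile 42.8, with Atrx at 74.9 and 96.0 TPM and Suz12 at 53.3 and 81.6 TPM. DNA repair genes (22 members) had a median of 0.55 at percentile 51.3. Chek1 stood at 448 and 597 TPM, Mdm4 at 238 and 448 TPM, and Palb2, the BRCA2 partner under the rule, at 7.24 and 15.5 TPM.

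The listed genes of energy metabolism and stress responses lay near the random lists as well. They were a small part of some lists: 10 of 83 respiratory chain, 14 of 81 ribosomal protein and 10 of 43 antioxidant genes. The other genes of these lists were not analysed, so the percentiles do not describe the whole pathways. Nuclear-encoded respiratory chain subunits (8 members) had a median of 0.62 at percentile 77.5, with Cox5a at 173 and 315 TPM and Cox5b at 145 and 227 TPM. Glycolysis and tricarboxylic acid cycle genes (12 members) had 0.52 at percentile 37.1, with Pdhb at 57.5 and 92.8 TPM and Dld at 44.2 and 53.5 TPM. Antioxidant enzymes (6 members) had 0.57 at percentile 49.9, with Glrx at 257 and 374 TPM and G6pdx at 34.5 and 62.4 TPM. Autophagy genes (11 members) had 0.48 at percentile 28.1, with Atg5 at 293 and 462 TPM. Unfolded protein and heat shock genes (7 members) had 0.51 at percentile 42.6. Pdia3 stood at 60.3 and 79.9 TPM, and Ern1, the endoplasmic reticulum stress sensor under the rule, at 19.4 and 42.6 TPM. Apoptosis regulators (8 members) had 0.57 at percentile 47.8, with Bik at 12.4 and 20.5 TPM and Birc3 at 13.6 and 18.2 TPM. Cytosolic ribosomal proteins (11 members) had 0.47 at percentile 26.7. The rule was met by Rpl7a (47.8 and 127 TPM) and Rps28 (4.13 and 39.0 TPM), and Rps14 stood at 97.3 and 118 TPM. Fertilization and egg surface genes (7 members, of which Atp2b1 met the rule) had 0.69 at percentile 73.1, with Snap23 at 37.97 and 46.54 TPM and a predicted variant of the zona protein gene Zp2 at 20.5 and 39.3 TPM. Zygotic genome activation genes (8 members) had 0.67 at percentile 82.4, with Zfp706 at 497 and 709 TPM, Sp110 at 211 and 327 TPM, and Arg2, under the rule, at 14.5 and 32.8 TPM. None of the 13 mitochondrially encoded mRNAs was among the transcripts analysed.

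The comparison of aged-sec with aged oocytes addresses whether secretome during maturation alters the mRNAs that were higher with age. Few transcripts differed by the size rule. It was met by 66 transcripts lower in aged-sec oocytes, of 63 genes, and by 5 higher, of 5 genes, among 2239 with enough TPM. The lower ones were led by Atad2 (15.4 TPM in aged and 0.01 in aged-sec oocytes), a variant of Atp2b1, a plasma membrane calcium pump (21.8 and 0.30 TPM), a variant of the splicing kinase gene Clk2 (14.0 and 0.07 TPM), and Timeless (15.2 and 0.13 TPM). They were followed by variants of Tdrp (30.6 and 1.3 TPM), Nfrkb (16.6 and 0.59 TPM), Hddc3 (65.2 and 4.02 TPM) and Tspan9 (11.1 and 0.96 TPM). The 5 higher ones were variants of the sheddase gene Adam10 (1.12 and 10.1 TPM), Suco (5.41 and 16.7 TPM), Tiam1, a Rac activator (10.6 and 27.1 TPM), Ccar1 (7.49 and 15.8 TPM), and Otud4 (6.26 and 13.0 TPM). Of the 66 lower transcripts, 29 were also at least 2-fold higher in aged than in young oocytes, or 43.9%, and 49 ended at or below the young value, or 74.2%. The aged library enters both comparisons, so a chance high aged value gives such overlaps without an effect. Simulated unchanged libraries with deviations resampled from the data, described next, gave 65.2% (95% range 45.0 to 87.4) and 66.7% (49.9 to 88.3). The observed 43.9% lay just below the first range and the 74.2% inside the second. With normal noise they gave 0% (0 to 100) and 100% (50 to 100), from a median of 2 transcripts per simulation.

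Over all 9126 listed transcripts, those under the size rule included, 6439 (70.6%) were lower in aged-sec than in aged oocytes, 2594 were higher and 93 were equal. The median aged-sec over aged ratio was 0.82 (interquartile range 0.59 to 1.04). Since each transcript entered the list through a high aged value, 3 unchanged libraries were simulated and kept at the same ratio of 1.2. They gave 72.6% of transcripts below aged (95% range 71.1 to 74.1) and a median ratio of 0.793 (0.778 to 0.808). With deviations resampled from the data they gave 72.1% (70.3 to 73.8) and 0.787 (0.768 to 0.803). The observed ratio lay above both ranges, on the side of a smaller shift, while the observed percentage lay below the first range and inside the second. The simulated sets were richer in low transcripts, so these pooled values do not compare like TPM levels. With normal noise a median of 2892 transcripts were kept, and a median of 1297.5 lay under 1 TPM, against 3074 of 9126 observed. The observed ratio was 0.75 for transcripts under 1 TPM in aged oocytes, 0.86 from 10 to 100 TPM, 0.91 from 100 to 1000 TPM and 1.02 for the 40 transcripts at 1000 TPM or more. Unchanged libraries gave a similar rise up to 1000 TPM, with 0.756, 0.848 and 0.873, and then 0.863 (0.701 to 1.01) over a median of 6 transcripts. With normal noise the observed ratio lay inside the simulated range at each level under 100 TPM, and just above it at higher levels. With resampled deviations it lay above the range from 1 to 100 TPM, and within its limits at the other levels. With the listed transcripts scaled to equal medians, which moved the median log2 ratio of this pair by 0.29, the split became 15 higher and 28 lower, and with upper-quartile scaling 10 higher and 31 lower.

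**Figure D1:**
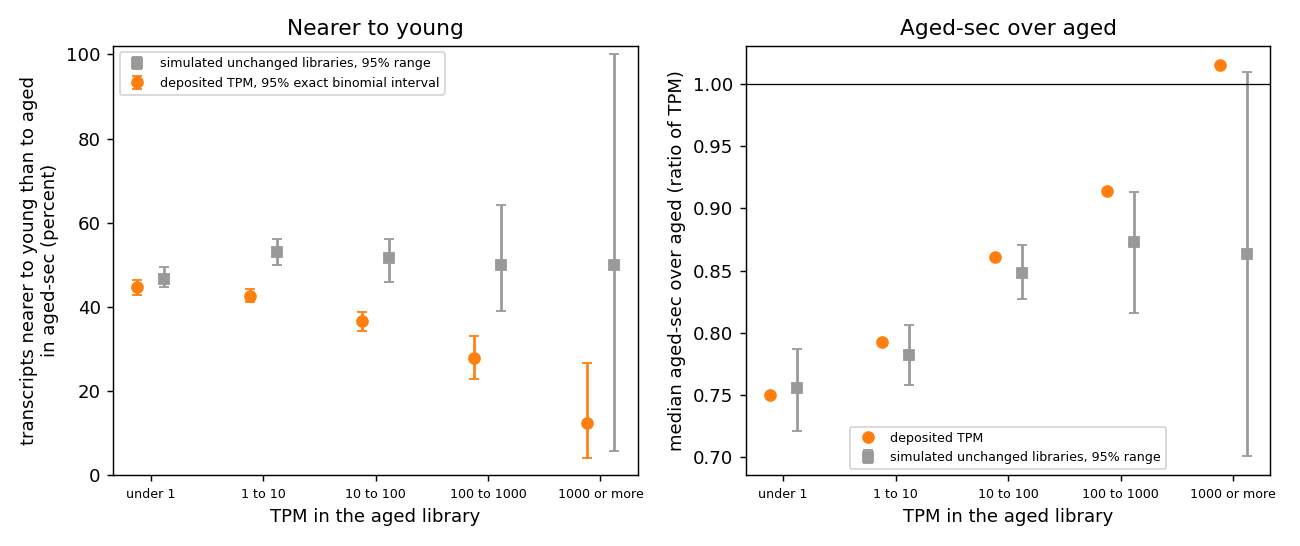
Percent of listed transcripts nearer to young than to aged in the aged-sec library (left, with 95% exact binomial intervals) and median aged-sec over aged ratio of TPM (right), by the TPM of the transcript in the aged library. Orange points are the deposited values and grey squares 100 simulations of 3 unchanged libraries with their 95% range. The observed share runs from 44.7% under 1 TPM to 12.5% at 1000 TPM or more, and the ratio from 0.75 to 1.02.

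For the MAP kinase cascade and its feedback genes, the pathway named in the study's title, the 11 detected members had a median log2 aged-sec over aged ratio of 0.03, against −0.25 in random lists, at the upper limit and not beyond it. In 20 further draws of random lists, made after this was seen, its percentile ran from 96.95 to 97.61 and passed the limit in 1. Of them 6 were above and 5 below the aged value, and none met the size rule. Rasa1 stood at 33.1, 46.8 and 50.5 TPM in young, aged and aged-sec oocytes, and Spred2, a feedback inhibitor of the cascade, at 7.82, 20.9 and 24.7 TPM. In the age comparison this list had a median of 0.44 at percentile 13.1, with Spred2 alone under the rule. With detection at 10 TPM, which leaves 4 members, that median was 0.88 at percentile 93.4, on the other side of its random lists. The BDNF and neurotrophin list (6 detected members) had medians of 0.70 in the age comparison and −0.08 against aged, at percentiles 77.5 and 84.1. Pik3r1 stood at 25.6, 41.9 and 35.9 TPM and Gab1 at 15.9, 27.9 and 32.7 TPM. Ntrk2, the BDNF receptor gene, was near the floor at 0.09, 0.16 and 0.10 TPM. Bdnf, Ngfr, Mos, Mapk3 and Zp3 were not analysed here.

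No fixed list stood apart between aged-sec and aged oocytes, and 18 of the 19 medians were below 0. Under median-of-ratios scaling, which moves all of them up together, 6 of the 19 were below 0. The lowest median was that of the chromatin regulators, −0.40 at percentile 4.8, where 16 of 20 members were below aged. With curated transcripts only it was −0.27 (percentile 33.5), and with detection at 10 TPM −0.25 (percentile 31.6). In both of these settings the unfolded protein list was lower, at −0.34. Crebbp went from 26.1 to 12.9 TPM, which did not reach the size rule. Spindle and kinetochore genes had a median of −0.32 at percentile 3.2, with 21 of 22 members below aged. Aurkc stood at 715 and 634 TPM and Kif23 at 276 and 211 TPM, while Ttk was the exception at 18.9 and 32.4 TPM. Under both scalings of the listed transcripts this list passed the limit, at percentiles 2.0 and 2.2, and with curated transcripts only it lay at percentile 23.6. The metaphase II and cell cycle list had −0.25 at percentile 15, and Cdc27 (NM_001285989), a subunit of the anaphase-promoting complex, was its only member under the size rule, at 37.3 and 8.58 TPM. The decay machinery had −0.22 at percentile 41.5. Edc4, a decapping scaffold, met the rule at 16.3 and 6.67 TPM, while Cnot6l stood at 67.4 and 74.5 TPM, Cnot7 at 584 and 535 TPM and Pabpn1l at 313 and 339 TPM. Oocyte maternal factors had −0.13 at percentile 61.7, with Bmp15, an oocyte growth factor, at 585, 817 and 799 TPM in young, aged and aged-sec oocytes. Of Gdf9 the table held 1 predicted variant, at 4.36, 6.81 and 4.46 TPM.

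Medians of the other lists between aged-sec and aged oocytes ran from −0.35 for antioxidant enzymes (percentile 24.5), with 6 of 6 members below aged, to −0.14 for apoptosis regulators (percentile 73.7). The unfolded protein list had −0.34 (percentile 14.8), cohesin −0.29 (17.8), fertilization and egg surface −0.27 (42.8), proteasome −0.24 (39.4), autophagy −0.23 (39.9), and ribosomal proteins −0.21 (39.6). Glycolysis and tricarboxylic acid cycle genes had −0.20 (percentile 52.2), the respiratory chain −0.19 (47.2), DNA repair −0.17 (73.1) and zygotic genome activation −0.17 (52.1). With detection at 10 TPM the fertilization and egg surface list, then with 3 members, moved to −0.92 and stood apart (percentile 0.8). Within these lists Atp2b1 was the member under the size rule. Pttg1, in the cohesin list, stood at 1943 and 1392 TPM, against 1388 TPM in young oocytes.

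**Figure D2:**
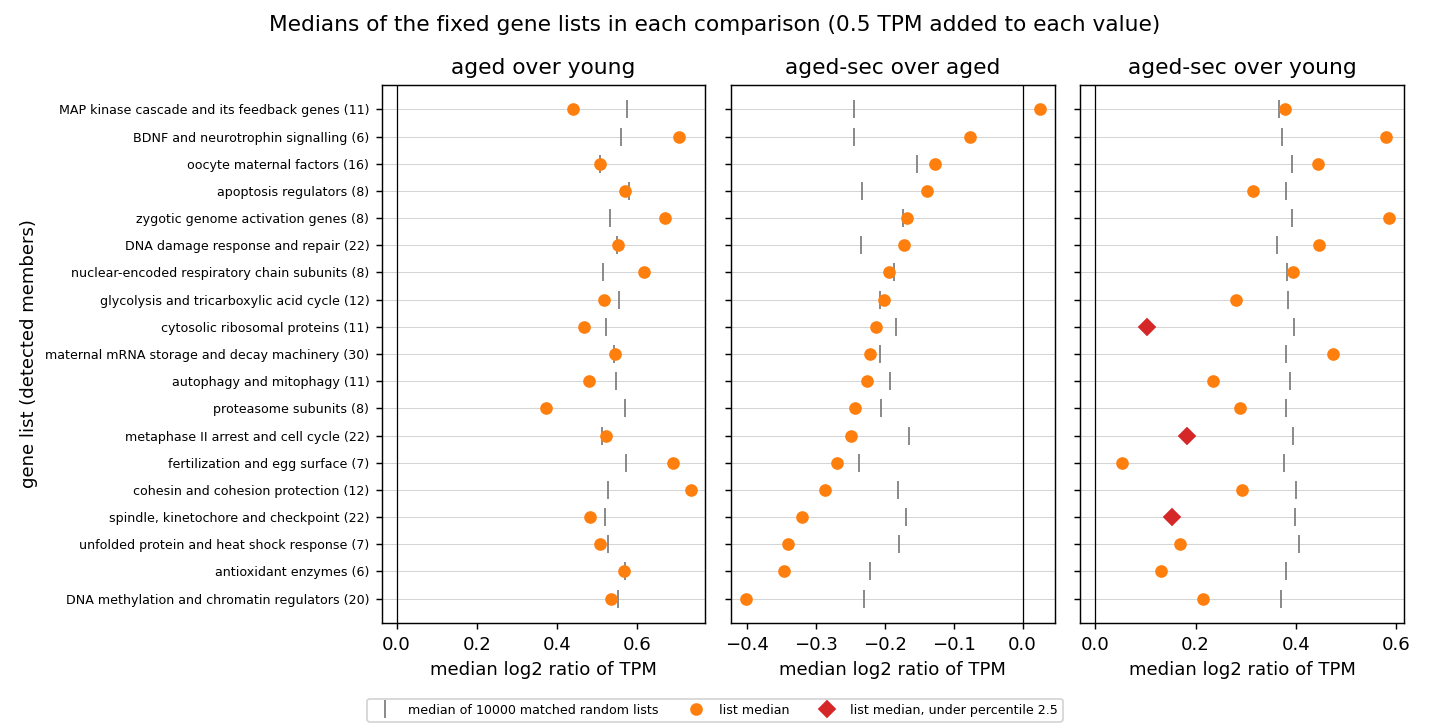
Median log2 ratio of the detected members of each of the 19 fixed gene lists in the 3 comparisons, with 0.5 TPM added to each value. Orange circles and red diamonds are list medians, the diamonds those under percentile 2.5, and grey ticks are medians of 10000 random lists matched on expression. The 3 diamonds are all in the comparison of aged-sec with young, and under scaling of the listed transcripts, which lowers all ratios of that comparison, their medians turn below 0.

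The third comparison addresses how near the treated aged oocytes came to young ones. Of the 398 transcripts at least 2-fold higher in aged than young oocytes, 224 or 56.3% were also at least 2-fold higher in aged-sec than young oocytes. Both ratios share the young library, whose low values help to select the set. Unchanged libraries with resampled deviations gave 10% (95% range 0 to 24.9), and those with normal noise gave 0% (0 to 45.4) from a median of 2 transcripts per simulation. At or below the young value in aged-sec oocytes were 3.0% of the 398, against 28.8% (13.6 to 51.1) with resampled deviations and 0% (0 to 86.2) with normal noise. In all, 341 transcripts of 274 genes met the rule as higher in aged-sec than young, and 9 as lower. Low young values also help to select the table, which favours the higher side without an effect. Simulated unchanged libraries with normal noise had 27.6% of all transcripts at or below young (95% range 25.9 to 29.2), against 24.2% observed. No simulated count under the rule was made for this pair. With median-of-ratios scaling the split by the rule was 85 higher and 34 lower, and with upper-quartile scaling 80 and 42. The higher ones were led by Cd55 (0.32 TPM in young and 106 TPM in aged-sec oocytes), Farsb (0.55 and 66.7 TPM), and variants of Fnip1 (0.12 and 15.5 TPM), Tiam1 (0.64 and 27.1 TPM), Zc3h14 (0.22 and 14.3 TPM), Suco (0.65 and 16.7 TPM), Ss18 (0.67 and 15.5 TPM) and Adam10 (0.30 and 10.1 TPM). Of the 9 lower ones the naming rule took 8, variants of Clk2 (11.3 and 0.07 TPM), Tdrp (22.8 and 1.3 TPM), Nfrkb (11.3 and 0.59 TPM), Cdc27 (25.3 and 8.58 TPM), Arhgap12 (13.4 and 5.00 TPM), Rrm2b (19.9 and 7.72 TPM), Cers2 (11.6 and 4.60 TPM) and Ccdc14 (28.3 and 13.4 TPM). The last, named after its values were seen, was a variant of Api5 (20.5 and 9.81 TPM). All 9 were also lower in aged-sec than in aged oocytes, which the selection of the table fixes, since each aged value lies above the young one.

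On the log2 scale, 54 of the 398 age-differing transcripts, 13.6% (95% exact binomial interval 10.4 to 17.3, over transcripts, which are not independent), were nearer to young than to aged in the aged-sec library. In 117 of the 398 the aged-sec value was above the aged one. The 3 simulated unchanged libraries gave 50% over all transcripts kept (95% range 48.0 to 52.0), against 41.5% observed over the whole list. With deviations resampled from the data, a median of 434 transcripts per simulation were kept at 10 TPM or more in aged, against 2186 observed. A median of 23 per simulation met the size rule, with 76.0% nearer to young (95% range 61.1 to 94.6). With normal noise a median of 2 met it, with 59.8% nearer to young and a range of 0 to 100 that covers the observed share. Among transcripts of at least 10 TPM in aged oocytes the observed share was 51.9% where aged over young lay between 1.2 and 1.3, and 13.1% where it lay between 2 and 4. The median aged-sec over aged ratio was 0.887 and 0.881 in the same ranges. Without the TPM minimum the share under the 2-fold rule was 25.8%, and at 50 TPM or more it was 7.2%.

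**Figure D3:**
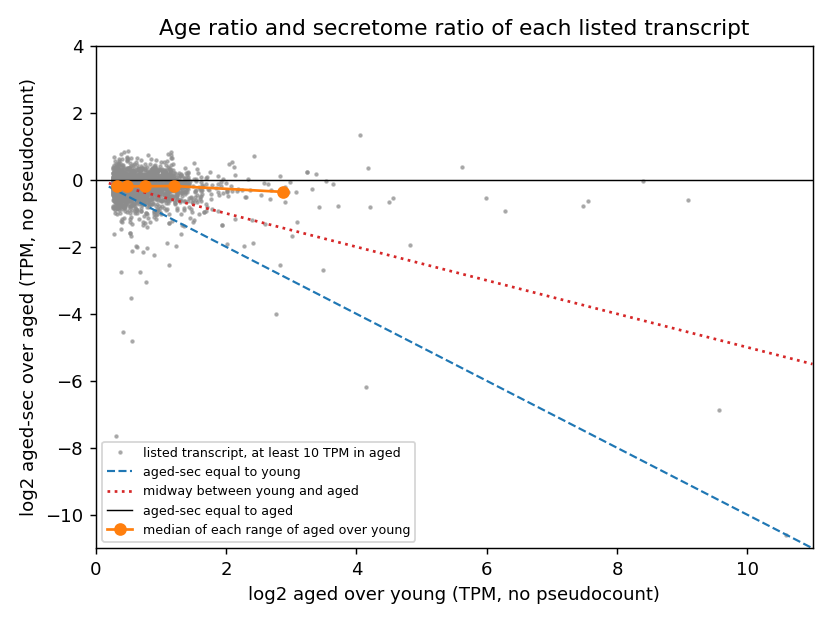
Log2 ratio of aged over young (horizontal) against log2 ratio of aged-sec over aged (vertical) for the 2186 listed transcripts with at least 10 TPM in the aged library, from TPM with nothing added. Lines mark an aged-sec value equal to aged, equal to young, and midway between them, and orange points are medians over 5 ranges of the age ratio. The medians lie at ratios of 0.887, 0.875, 0.876, 0.881 and 0.78 from the lowest range to the highest.

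Between aged-sec and young oocytes 3 of the 19 fixed lists stood apart, all with smaller excesses than their random lists, where 0.95 would by chance. None stood apart in either of the other comparisons, where 0.95 would by chance in each, so the count over all comparisons is near the chance number. Spindle and kinetochore genes had a median log2 ratio of 0.15 against 0.40 in random lists (percentile 0.8), with 15 members above and 7 below young. Examples of those below young are Kif23, at 213 TPM in young and 211 TPM in aged-sec oocytes, Bub3, at 65.8 and 52.7 TPM, and a predicted variant of Tacc3, at 75.2 and 50.9 TPM. Aurkc, the most abundant member, and Ttk, whose values are given above, were higher in aged-sec than in young oocytes. Ttk alone of the list met the size rule in this comparison. Bub3 and Tacc3 were chosen after their values were seen. Metaphase II and cell cycle genes had 0.18 (percentile 1.7) and cytosolic ribosomal proteins 0.10 (percentile 2.4). In the cell cycle list Ccnb1, chosen in the same way, stood at 1643 and 1754 TPM, while Cks2 stood at 7430 and 11674 TPM. Among ribosomal proteins Rps14 stood at 97.33 and 104.62 TPM, while Rps28 stood at 4.13 and 45.7 TPM. In 20 further draws of random lists the spindle and metaphase II lists stood apart in all 20 and the ribosomal list in 16. With random lists not matched on expression none of the 19 stood apart, and the spindle list then lay at percentile 2.8. With detection at 10 TPM the spindle list had 0.16 (percentile 1.8), while the metaphase II list had 0.41 (percentile 43.4) and the ribosomal list 0.67 (percentile 96.2), on the other side of its random lists. With a pseudocount of 2 TPM the metaphase II list (percentile 3.0) and the ribosomal list (3.1) no longer stood apart. The same held under median-of-ratios scaling (5.5 and 7.5) and upper-quartile scaling (6.6 and 8.0), and for the ribosomal list with curated transcripts only (4.2).

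The other lists had medians from 0.05 to 0.59 in this comparison. Fertilization and egg surface genes (0.05, percentile 5.6), antioxidant enzymes (0.13, 10.6), the unfolded protein list (0.17, 11.3), chromatin regulators (0.21, 11.9), autophagy (0.24, 14.9), glycolysis (0.28, 22.8), proteasome (0.29, 29.5), cohesin (0.29, 22.8) and apoptosis regulators (0.31, 37.3) lay below the random median. The MAP kinase list (0.38, percentile 52.7), the respiratory chain (0.39, 53.0), oocyte maternal factors (0.44, 68.4), DNA repair (0.45, 75.9), the decay machinery (0.48, 84.0), the BDNF list (0.58, 82.1) and zygotic genome activation (0.59, 86.6) lay above it.

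Markers of other cell types could be followed only where the table lists them, and the levels of the others were not analysed here. Of 31 cumulus and granulosa markers 6 were listed and 3 detected, the highest being Serpine2, at 421, 517 and 409 TPM in young, aged and aged-sec oocytes, of sums of 424, 523 and 413 TPM. The 5 listed of 20 theca and stroma markers summed to 2.56, 6.49 and 4.62 TPM, led by Dcn at 2.22, 4.03 and 3.08 TPM, and the 4 listed of 13 endothelial markers to 6.14, 10.8 and 6.94 TPM, led by Flt1 at 3.39, 4.87 and 3.05 TPM. The only listed blood marker was at 0.01, 0.02 and 0.01 TPM, and the only surface epithelium marker, Epcam, was at 1.36, 2.23 and 1.28 TPM. Of the 14 mesenchymal stem cell markers 0 were listed.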

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

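The alternatives that added or removed pseudocounts, curated transcripts, second copies or sums per gene, and for the share nearer to young no TPM minimum and removal of ribosomal protein genes, were chosen after the data were seen. Of 78 recomputed counts of transcripts 35 stayed within 1.5 times the reported value. No setting gave a transcript lower in aged than young, which the table excludes, so every such count is among the 35 by construction. With each scaling, TPM minimum or fold limit, without a minimum, and with curated transcripts only, no other count stayed within that range. Removing ribosomal protein genes, second copies or the pseudocount left all counts within that range. All 74 recomputed ratios of named transcripts kept their direction, and 8 no longer met the size rule. Their direction could not have changed. These log2 ratios were at least 1 in size, the scaling used moved them by less, and a pseudocount added to both values cannot turn a ratio. Of the recomputed list medians, added families included, 358 stayed within the 95% interval of the reported median, 122 moved out of it and 6 changed sign in lists that stood apart. Depth is unknown and cannot be varied.

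The scalings bring the listed transcripts of the libraries to a common level, by the median of their ratios or by their upper quartiles, which removes most of an excess that the table's selection fixed. They moved the median log2 aged over young by −0.79 and −0.79, aged-sec over aged by 0.29 and 0.25 and aged-sec over young by −0.50 and −0.54. With median-of-ratios and upper-quartile scaling, 56 and 57 transcripts were higher in aged than young (398 reported), 15 and 10 higher (5 reported) and 28 and 31 lower (66 reported) in aged-sec than aged, and 85 and 80 higher (341 reported) and 34 and 42 lower (9 reported) in aged-sec than young. The share nearer to young was 19.6% and 19.3%.

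Thresholds moved the counts by construction. Higher in aged than young were 1284 transcripts at 1 TPM, 1364 with no minimum, 83 at 50 TPM, 1041 at 1.5-fold and 54 at 4-fold. Higher in aged-sec than aged were 45, 45, 0, 40 and 1 in that order, and lower 484, 522, 3, 254 and 16. Higher in aged-sec than young were 960, 1022, 75, 749 and 40, and lower 69, 76, 0, 17 and 3. The share nearer to young was 26.2%, 25.8%, 7.2%, 21.2% and 18.5%. Curated transcripts only gave 223 higher in aged than young, 2 higher and 39 lower in aged-sec than aged, and 178 higher and 5 lower in aged-sec than young. A pseudocount of 2 TPM left 3 higher in aged-sec than aged, and sums per gene left 3 higher and 42 lower. With curated transcripts only fewer rows entered, and with the pseudocount of 2 TPM low ratios shrank. Sums per gene add the other listed variants of a gene to the variant that met the rule. The 66 lower transcripts came from 63 genes, so fewer rows alone do not account for the 42.

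The number of fixed lists standing apart in aged against young was 1 with curated transcripts only (0 reported), the cohesin list. In aged-sec against aged it was 1 with each scaling, the spindle list, and 1 with detection at 10 TPM, the fertilization and egg surface list (0 reported). In aged-sec against young (3 reported) it was 1 with each scaling, with detection at 10 TPM and with a pseudocount of 2 TPM, each time the spindle list, and 0 with unmatched random lists. The medians of these 3 lists turned negative with median-of-ratios and upper-quartile scaling, to −0.33 and −0.36 for the spindle list, −0.25 and −0.27 for the metaphase II list and −0.33 and −0.35 for ribosomal proteins, as the shift of the whole comparison requires. With detection at 10 TPM the metaphase II list moved from 0.18 to 0.41 (percentile 43.4) and the ribosomal list from 0.10 to 0.67 (percentile 96.2), with 14 and 8 members left. The cause of the other changes was not tested.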

Other observations

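Of 8 gene families chosen after the data were seen, the Nlrp and Zfp genes stood apart from random lists in the age comparison and the Obox and Sm and LSm genes between aged-sec and aged oocytes. The Nlrp family had the highest median log2 aged over young of the added families, 0.98 over 10 detected members (percentile 100, and 99.9 with curated transcripts only). Of these members 5 met the size rule, among them Nlrp4f, Nlrp9a (64.9 TPM in young, 135 TPM in aged and 122 TPM in aged-sec oocytes) and a predicted variant of Nlrp9b (31.5, 117 and 84.6 TPM). In aged-sec against young the family median was 0.95 (percentile 99.9). Genes named Zfp, mostly zinc finger transcription factors, had 0.68 over 132 members (percentile 99.1), and in aged-sec against young 0.54 (percentile 100). Members of these families are near-identical copies in part, and reads can be shared among them.

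The most abundant listed transcripts, those of at least 1000 TPM in aged oocytes, had a median aged-sec over aged ratio of 1.02, against 0.82 over the list. Simulated unchanged libraries gave 0.863 (95% range 0.701 to 1.01) with normal noise and 0.852 (0.733 to 1.029) with resampled deviations, each over a median of 6 transcripts, against 0.793 over the list. The Obox homeobox genes had a median log2 aged-sec over aged of 0.29 (percentile 99.9), with 4 of 4 detected members above aged. Obox2 stood at 10491, 18633 and 20323 TPM in young, aged and aged-sec oocytes and Obox5 at 13442, 16166 and 18664 TPM. Spliceosomal Sm and LSm proteins had 0.15 over 8 members (percentile 99.4), with Snrpg at 3802, 4931 and 6013 TPM and Snrpe at 3083, 4309 and 4615 TPM, and 6 of 8 above aged. Their matched random lists had negative medians, −0.09 for Obox and −0.14 for Sm and LSm genes. The transcripts of at least 1000 TPM, these 4 named ones among them, had the ratio of 1.02. The match may not reach the level of these named members, so both percentiles may in part follow abundance. With detection at 10 TPM the Obox genes no longer stood apart, with a median of 0.21 over 3 members (percentile 96.3), and the Sm and LSm proteins did, with 0.21 over 6 members (percentile 99.6). The Fbxw family had 0.05 (percentile 96.1), the Oog family −0.03 (74.5), the Tcl1 family −0.10 (53.4), and Rfpl4 −0.13 (40.3). These 4 lay within the range of matched random lists, and the Fbxw family stood apart (percentile 99.0) with random lists not matched on expression.

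All tests in the following paragraphs were chosen after the results were seen. Their 95% intervals run over transcripts, which are not independent, and hold no error between libraries. Transcripts at least 2-fold higher in aged than young oocytes mostly stayed above young in aged-sec oocytes. A chance high value of the aged library alone would bring their aged-sec over young ratio back to about 1. Low young values also enter the selection, and simulated unchanged libraries gave 1.22 (95% range 0.995 to 1.47) with resampled deviations and 1.41 (0.927 to 1.84) with normal noise. The median ratio was 2.26 (95% interval 2.17 to 2.35 over 398 transcripts), with 386 above young, which argues against chance in the aged library alone. A young library that stands apart from the others for a technical reason may give the same picture, and a chance low young value raises the same ratio. The rank correlation across transcripts was 0.957 for aged with aged-sec, 0.965 for aged with young and 0.94 for aged-sec with young. These values do not decide it, because the transcripts were selected on the ratio of aged over young, which bears on that pair directly. With 1 library per group age and library cannot be told apart. A lasting effect of age that the secretome does not alter is the biological explanation in the design and was not tested.

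Most listed transcripts were lower in aged-sec than aged oocytes, with a median ratio of 0.818. A larger part of all TPM taken by the 40 transcripts of at least 1000 TPM is argued against: it left the others a factor of 0.987, while their median ratio was 0.817 (95% interval 0.808 to 0.824). Simulated unchanged libraries gave 0.793 (0.778 to 0.808), a shift slightly larger than the observed one, in sets richer in transcripts under 1 TPM. Selection on a high aged value may therefore account for the shift. It cannot be told apart from a mild effect of the secretome, because the noise in that simulation came from the same ratios and no replicate measures it. A reduction of maternal mRNA by the secretome stays open and untested.

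Most transcripts with the largest ratios between aged-sec and aged oocytes were single variants of their gene. Of the 71 transcripts under the size rule, 97.2% (95% interval 90.2 to 99.7) came from genes with several RefSeq mRNAs, against 85.5% of transcripts matched on TPM, which is in line with reads divided differently among the variants of a gene, by the quantification or in the oocyte. Summing the listed variants of each gene, described above, still left most of the number of lower ones under the rule. Whether these were the same genes was not examined, and unlisted variants could not be added. Of the 71 transcripts 2 came from genes with a single mRNA in the RefSeq annotation used here, Atad2 and a gene named only by an identifier. For them the explanation would not hold, unless the authors' quantification, whose annotation is not known, had further variants. Second genomic copies made up 2 of the 71, 2.8%, and so do not account for the set. A biological switch between variants after secretome was not tested.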
